A study of Mus musculus with 6 samples.

How the data were processed

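Nuclei of mouse brain were profiled by PIPseq in 6 libraries, 2 from dentate gyrus with a control virus, 2 from dentate gyrus with a Cre virus and 2 from whole forebrain of mice aged 74 weeks. Per the labels, nuclei were released by douncing and polyadenylated RNA was sequenced. The authors deposited, for each library, a matrix of raw UMI counts per gene and barcode, whole numbers without normalization, for barcodes that they had already selected. The submitters' notes name mm10 and Cell Ranger without a version or role. The aligner, the counting tool and the annotation release are not given in the sources used here. The dentate matrices list 55422 features and the forebrain matrices 32227, and dentate and forebrain values were not compared for that reason. Positions come from GENCODE vM21 on GRCm38, in which 99.5% of the mouse features of the dentate files and 99.6% of those of the forebrain files were found by identifier.

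Nuclei were kept with at least 500 UMIs and at most 5% of UMIs from mitochondrial genes. A doublet score after Scrublet was computed for each library. Its automatic threshold marked almost no nuclei, so nuclei scoring above the value at rank 6%, the expected doublet rate, were removed, which was 5.40% to 5.94% per library because scores were tied. Dentate and forebrain nuclei were clustered separately from analytic Pearson residuals (theta 100, clipped at 10) of 2000 selected genes. Genes of the fixed lists, mitochondrial and ribosomal genes were left out of the selection, as were genes that share reads with a neighbour (25 in dentate, 92 in forebrain). The steps after that were 30 principal components, a reimplementation of Harmony with libraries as batches, 15 nearest neighbours and Leiden clustering at resolution 1, with seed 1. Clusters were named from fixed markers of 22 cell classes. A name needed at least 3 markers and 33.3% of the class's markers at 1.5-fold or more over the other clusters, a lead of at least 2 markers or 15% of markers over the next class, and a check of the 10 top genes of the cluster. Clusters of fewer than 30 nuclei were not named. Mixed forebrain clusters of at least 200 nuclei were split again. Splitting did not part the marker sets in the dentate, so it was used in the forebrain alone. A class name ends in "-like" because it rests on RNA alone.

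Nuclei are not replicates, so counts were summed per library and class. In the dentate, p-values measure the spread between libraries. The labels do not say which animals lie behind the libraries. All classes come from the same libraries and are not independent of each other. Sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), Cre virus against control virus, in classes with at least 50 nuclei in each of the 4 dentate libraries. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The difference between granule neuron-like nuclei and the other named classes together was an interaction term with the library as a block. For 29 fixed gene lists, limma 3.58.1 camera (preset correlation 0.01) was run, with an estimated correlation and fry as alternatives. In aged forebrain each class was tested against the mean of the others with the library as a block. The spread there was pooled over the sums of all tested classes of 2 libraries. Its SE and p-values therefore do not measure how far a single class differs between libraries. Where 1 library was left out, the spread came from the group that kept 2. DESeq2 1.42.0 served as the other tool. R was 4.3.3, Python 3.11.15 and scanpy 1.11.5.

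Cell class shares are percentages of kept nuclei with Wilson 95% intervals, compared with an exact two-sided permutation test. Intervals and floors (3 counts of the total) cover counting error only. Totals per library range from 10005157 to 169003216 UMIs in kept nuclei. On simulated libraries with the spread of the data, edgeR recovered 16% of genes changed 2-fold and 88% of genes changed 4-fold in granule neuron-like nuclei, and 7% and 80% over all nuclei. For the difference between classes it recovered 40% and 78%, and in aged forebrain 66.3% and 96.0%. With a fixed dispersion of 0.05 instead, it recovered 1% and 42% for the difference between classes and 30.1% and 92.9% in aged forebrain. In granule neuron-like nuclei it then recovered 30% and 95%, and over all nuclei 27% and 97%. Small changes in the dentate were therefore mostly out of reach. The genes changed in the simulations were drawn from well-counted genes, so these rates do not cover genes with few counts.

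Except for the doublet cut and cluster splitting, the groups, tests, markers, lists, thresholds and 47 alternatives were fixed before the data were examined. Genes were named by a rule fixed then as well. For granule neuron-like and all nuclei these are genes past the threshold whose Cre virus libraries both lie on the same side of both control virus libraries, with a mean of at least 5 CPM and without predicted or clone names. As fewer than 10 passed, the 8 smallest p-values in each direction with the same conditions are named as not passing. In the other classes the 4 smallest p-values past the threshold in each direction are named, and per list up to 4 genes with the smallest p-values in the dentate or the largest fold changes, at 20 CPM or more and not class markers, in aged forebrain. Some genes and 1 gene list are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Replicates were checked not to be copies of each other. Groups of 2 libraries were too small for a search for outlying samples and for counts over other splits of the samples.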

Results

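The series holds 6 single-nucleus RNA libraries of mouse brain, 2 in each of 3 groups. They were made with PIPseq, an assay that catches nuclei with barcoded beads in an emulsion formed without a microfluidic chip. The dentate gyrus gave 4 libraries, 2 labelled control virus and 2 labelled Cre virus, where Cre is a recombinase that removes DNA lying between loxP sites. The remaining 2 libraries came from the whole forebrain of mice aged 74 weeks. The labels name neither the gene carrying loxP sites, nor the reporter, the virus type, or the sex of the animals, and they do not say which animals lie behind which library.

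The control virus libraries held 21889 and 16068 deposited barcodes with 30344769 and 34335259 UMIs in total. The Cre virus libraries held 47369 and 16384 barcodes with 49810841 and 15524565 UMIs. The aged forebrain libraries had the most UMIs in total, with 98320 and 22772 barcodes and 198551271 and 98065941 UMIs. After filtering, 15591 and 14970 control virus nuclei, 29985 and 9519 Cre virus nuclei, and 87038 and 21506 aged forebrain nuclei remained. Their median UMIs per nucleus were 1246 and 1823 for control virus, 963 and 815 for Cre virus, and 1560 and 3875 for aged forebrain. The smallest UMI count per deposited barcode differed between the dentate libraries, at 688 and 1115 for control virus against 480 and 415 for Cre virus. The median share of UMIs from mitochondrial genes in kept nuclei was 2.48% and 0.891% in control virus, 2.19% and 2.45% in Cre virus, and 0.685% and 0.0342% in aged forebrain.

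The first comparison asked whether RNA from the virus or a reporter marked the Cre virus nuclei. A feature named cre was listed in both control virus libraries and in Cre virus replicate 1, and it did not separate the groups. A feature named tomato, presumably a red fluorescent reporter, was listed in Cre virus replicate 2 alone, which listed no cre feature. Kept nuclei held 5 and 9 cre UMIs in the control virus libraries, or 0.227 (exact Poisson 95% interval 0.0737 to 0.530) and 0.290 (0.133 to 0.551) CPM. Cre virus replicate 1 held 3 cre UMIs, or 0.0847 (0.0175 to 0.248) CPM. No cre UMI was found in its 7880 granule neuron-like nuclei, which allows up to 0.0381% of nuclei with a UMI (3 nuclei of the total). Cre virus replicate 2 held 78 tomato UMIs in 77 of 9519 nuclei, or 7.80 CPM (6.16 to 9.73). The share of nuclei with a tomato UMI was 0.799% (Wilson 95% interval 0.542 to 1.18) in granule neuron-like nuclei, at a median of 665 UMIs, and 0.734% (0.528 to 1.02) in the other named classes, at a median of 925.5 UMIs. Per UMI counted, tomato lay at 10.3 CPM in granule neuron-like nuclei and 6.72 CPM in the other named classes, and this difference was not tested.

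None of the genes commonly studied with floxed alleles stood out as the deleted gene. Of the 30 such genes on the list, all were measured in granule neuron-like nuclei, and 3 lay higher and 27 lower in the Cre virus libraries. By edgeR, 0 of the 30 passed the threshold, over all genes or adjusted over the list alone, and 0 had an unadjusted p below 0.05. Kcnt1, a sodium-activated potassium channel (ENSMUSG00000058740, chromosome 2, 25863734 to 25918273), had a log2 fold change of -0.41 (SE 0.35). It did not pass with DESeq2. Deletion of an exon need not lower the reads counted over a whole gene, and nuclei that the virus did not reach are summed with those that it did.

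In granule neuron-like nuclei, the dentate cells that the study most likely aimed at, the comparison asked which genes differ with Cre. With the settings chosen first, the differences that passed were those of sex chromosome genes. More genes passed with a replicate block or with no filter on low counts. Xist, the noncoding RNA that silences an X chromosome in female cells, was abundant in both control virus libraries and almost absent from both Cre virus libraries. Eif2s3y, a Y-linked subunit of a translation initiation factor, showed the opposite. Of 15424 genes tested with edgeR, 2 passed a Benjamini-Hochberg adjusted p of 0.05, and 185 had an unadjusted p below 0.05, while DESeq2 called 7. Xist (ENSMUSG00000086503, X chromosome, 103460366 to 103483254 on GRCm38) measured 1438 and 1834 CPM in control virus and 0.15 and 1.57 CPM in Cre virus, where 1 and 4 UMIs were counted. It fell by 11.34 on the log2 scale (SE 0.92, adjusted p = 0.0207), in 2 of 2 Cre virus libraries. Eif2s3y (ENSMUSG00000069049, Y chromosome, 1010543 to 1028847) rose from 0.46 and 1.58 CPM to 144 and 152 CPM (log2 fold change 7.07, SE 0.48, adjusted p = 0.0119), in 2 of 2 Cre virus libraries. The count was 0 without control virus replicate 1 (1938 genes at unadjusted p below 0.05), with adjusted p = 0.105 for Xist (log2 fold change -11.56) and 0.107 for Eif2s3y (6.52). It was 0 as well without control virus replicate 2 (211 genes), with 0.136 for each (-11.23 and 8.20). The count rose to 49 without Cre virus replicate 1 and to 15 without Cre virus replicate 2.

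Further genes had both Cre virus libraries on the same side of both control virus libraries in granule neuron-like nuclei without passing. Among them were the Y-linked histone demethylases Uty (ENSMUSG00000068457), at 16.7 and 15 CPM against 76.9 and 104 CPM (log2 fold change 2.51, adjusted p = 0.245), and Kdm5d, at 0.46 and 3.95 CPM against 39.5 and 49.2 CPM (adjusted p = 0.321). Uty, Kdm5d and Serpinb1b passed without Cre virus replicate 1 (adjusted p = 1.77e-04, 4.23e-09 and 8.88e-05) and without Cre virus replicate 2 (0.00385, 2.00e-08 and 9.05e-06). A single nucleus held 20 of the 38 Uty UMIs of control virus replicate 2 and 11 of the 36 of replicate 1. Serpinb1b (ENSMUSG00000051029, chromosome 13, 33078575 to 33094380), a protease inhibitor gene, measured 11.6 and 18.2 CPM in control virus against 0.30 and 0 CPM in Cre virus (adjusted p = 0.245). Higher in both Cre virus libraries, each with adjusted p = 1.0, were Fam114a1 (log2 fold change 2.38), Olfr1346 (4.59), Rad21l (2.95), Dusp27 (2.14), Adnp2 (1.21) and Rbp2 (1.41). Lower in both, again with adjusted p = 1.0, were the ubiquitin ligase gene Pdzrn3 (-1.35), Tnfrsf11a (-1.77), Cryzl2 (-2.14), Olr1 (-1.89), Engase (-1.34), Ano1 (-1.32) and Tsix, which overlaps Xist on the other strand (-1.60). Olfr1346 and Rad21l passed without Cre virus replicate 1 (adjusted p = 8.56e-08 and 0.00598).

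Summed over all kept dentate nuclei, whatever their class, the same comparison with the settings chosen first again singled out sex chromosome genes. Xist was lower, and the Y-linked genes Eif2s3y, Kdm5d and Gm29650 were higher, in both Cre virus libraries. edgeR called 4 of 25878 genes, and 384 had an unadjusted p below 0.05, while DESeq2 called 9. Xist measured 969 and 1327 CPM in control virus and 0.87 and 1.81 CPM in Cre virus (log2 fold change -9.84, SE 0.75, adjusted p = 0.0198). Eif2s3y measured 0.44 and 0.95 CPM against 130 and 138 CPM (7.55, SE 0.47, adjusted p = 0.00808). Kdm5d (ENSMUSG00000056673, Y chromosome, 897788 to 956786) rose from 3.38 and 2.61 CPM to 36.0 and 40.7 CPM (3.68, SE 0.32, adjusted p = 0.0329). Gm29650 (ENSMUSG00000099876, Y chromosome, 1048393 to 1049134), a predicted gene named here after its values were seen, had 0 UMIs in both control virus libraries and 286 and 114 in the Cre virus libraries, at least 59.3-fold higher when each control virus library is set at its floor of 3 UMIs (adjusted p = 0.0348). Each call was seen in 2 of 2 Cre virus libraries. Kdm5d and Gm29650 did not pass without control virus replicate 2 (adjusted p = 0.10 for each), where the log2 fold change of Kdm5d was 3.49 and Gm29650 still had 0 UMIs in control virus. Leaving out 1 library at a time gave 5 calls without control virus replicate 1, 2 without control virus replicate 2, 105 without Cre virus replicate 1 and 6 without Cre virus replicate 2.

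Other genes lay on the same side in both Cre virus libraries over all dentate nuclei without passing. Higher, each with adjusted p = 1.0, were Fgfr3 (log2 fold change 1.0), Id4 (1.15), Sdc4 (1.12), Serpina3n (1.22) and F3 (0.95), and Fgfr3 is 1 of the markers used to name astrocyte-like nuclei. The granule neuron marker C1ql2 was also higher (1.04), as were the Y-linked Uty (2.24, adjusted p = 0.664, or 0.00347 without Cre virus replicate 1) and Ddx3y (1.72). Lower in both, with adjusted p = 1.0 for each, were Tsix (-1.23), the transcription factor genes Zic4 (-1.43) and Zic1 (-1.12), the cilium gene Wdr19 (-1.49), Cwh43 (-1.48), Zfp366 (-1.28), Slfn5 (-0.98) and Prkcd (-0.95). Zic4, Zic1 and Prkcd are among the top genes of an unnamed cluster with 176 and 256 nuclei in control virus and 74 and 37 in Cre virus. The shares of astrocyte-like and granule neuron-like nuclei differed between the same libraries as well, so sums over all nuclei carry differences in composition as well.

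**Figure D1:**
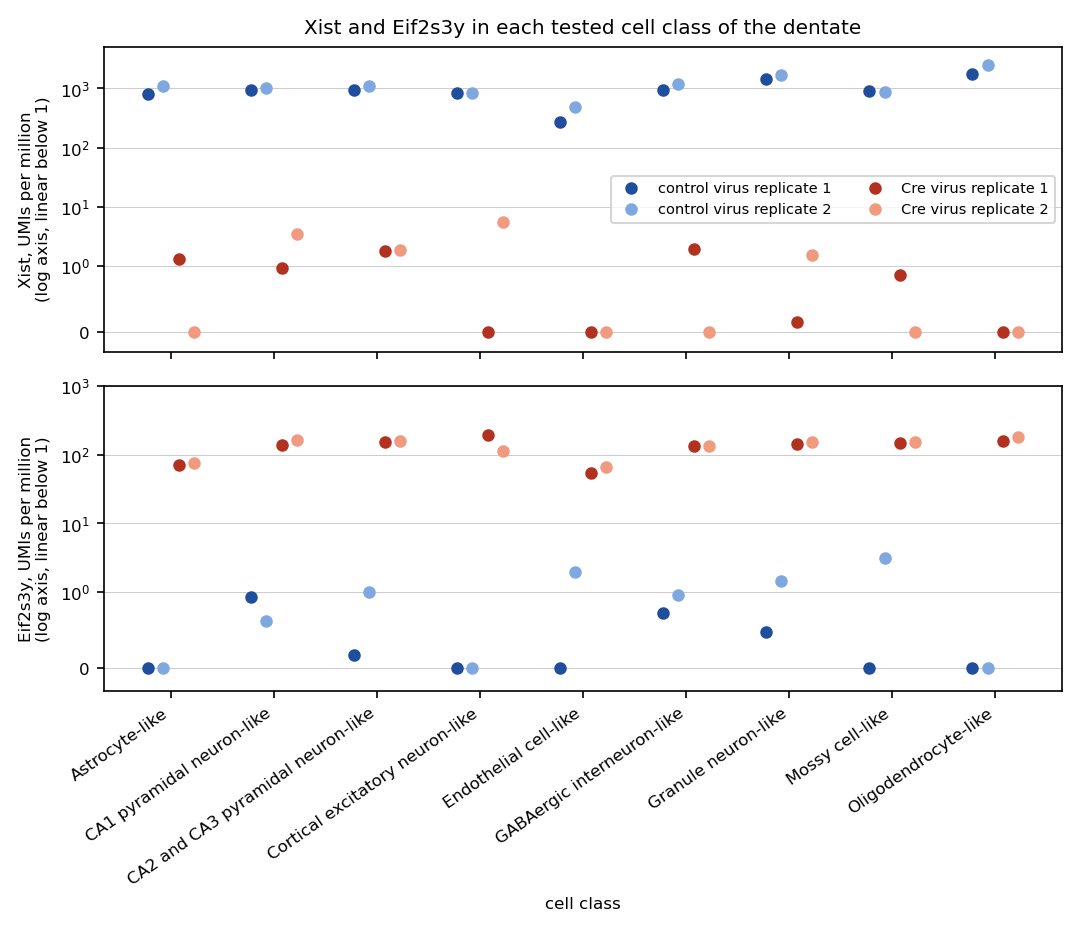
CPM of UMIs (log axis, linear below 1) of Xist and Eif2s3y in each tested cell class of the dentate, with a point for each control virus and Cre virus library. Xist lies between 272 and 2438 CPM in every tested class of the control virus libraries and at or below 5.63 CPM in the Cre virus libraries, while Eif2s3y lies at or below 3.12 CPM in control virus and between 54.0 and 195 CPM in Cre virus.

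Outside granule neurons the comparison asked whether any effect of Cre reached other dentate cell types. In 8 further classes Xist was the shared call, and Eif2s3y was called in all of them but oligodendrocyte-like nuclei. In that class Eif2s3y was still higher in both Cre virus libraries, without passing. Astrocyte-like nuclei also differed in a collagen gene, Col8a1. edgeR called 4 genes in astrocyte-like nuclei, 3 in CA1 pyramidal neuron-like, 2 in CA2 and CA3 pyramidal neuron-like, 2 in cortical excitatory neuron-like, 21 in endothelial cell-like, 3 in GABAergic interneuron-like, 2 in mossy cell-like and 1 in oligodendrocyte-like nuclei. Over these classes and granule neuron-like nuclei, a Xist count of 0 in a Cre virus library allowed up to 3.40 to 28.8 CPM, and a count of 0 for Eif2s3y in a control virus library allowed up to 2.71 to 29.8 CPM. Col8a1 (ENSMUSG00000068196, chromosome 16, 57624258 to 57754737) measured 29.2 and 91.9 CPM in control virus astrocyte-like nuclei and 7.99 and 4.43 CPM in Cre virus (log2 fold change -3.06, SE 0.56, adjusted p = 0.0235), lower in 2 of 2 Cre virus libraries. Col8a1 did not pass without control virus replicate 2 (log2 fold change -2.07, adjusted p = 0.792). Eif2s3y in cortical excitatory neuron-like nuclei did not pass without Cre virus replicate 1 (adjusted p = 0.424), with 20 UMIs in the other Cre virus library and 0 in both control virus libraries, nor did Xist in oligodendrocyte-like nuclei without Cre virus replicate 2 (adjusted p = 1.0), although 0 UMIs were counted in both Cre virus libraries.

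Call counts in these classes depended on which library was left out. Leaving out control virus replicate 1, they were 261 in astrocyte-like, 3 in CA1, 1095 in CA2 and CA3, 77 in cortical, 870 in GABAergic, 171 in mossy cell-like and 22 in oligodendrocyte-like nuclei. Leaving out control virus replicate 2, they were 7, 3, 7, 27, 5, 83 and 17 in the same order. Without Cre virus replicate 1 they were 45, 87, 77, 27, 64, 49 and 12. Without Cre virus replicate 2 they were 4, 11, 11, 15, 10, 11 and 0, the last by edgeR with 48 genes at unadjusted p below 0.05. DESeq2 was not run in these classes.

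Endothelial cell-like nuclei gave the most calls, and several of these rested on single nuclei of Cre virus replicate 2, which held 108 nuclei of the class. Pakap (ENSMUSG00000090053, chromosome 4), an A-kinase anchoring gene, measured 4.35 and 20.2 CPM in control virus and 17.7 and 680 CPM in Cre virus (log2 fold change 4.70, SE 0.79, adjusted p = 7.78e-06). In Cre virus replicate 2, 1 nucleus held 82 of its 90 UMIs. Adra1a, an adrenergic receptor gene, measured 4.35 and 12.1 CPM against 29.0 and 264 CPM (log2 fold change 3.90, SE 0.70, adjusted p = 5.73e-05), and 1 nucleus held all 35 of its UMIs there. Of the Uty UMIs in that library, 48 of 54 lay in 1 nucleus. With the top nucleus of each gene left out, 4 genes passed in endothelial cell-like nuclei. Without Cre virus replicate 2, Pakap (log2 fold change 0.51), Adra1a (1.77) and Uty (1.96) each had adjusted p = 1.0. Their adjusted p without control virus replicate 1 was 0.165, 0.120 and 0.141. The count was 41 without control virus replicate 1 and 119 without Cre virus replicate 1, against 22 and 18 without control virus replicate 2 and Cre virus replicate 2.

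The next comparison asked whether Cre acted differently on granule neurons than on the other named classes together. No single gene passed with the settings chosen first, against 1 with RLE scaling and 95 with no filter on low counts. The make-up of the other classes also differed between the groups, with a mean astrocyte-like share of all nuclei of 2.70% in control virus and 7.34% in Cre virus. The interaction test of edgeR called 0 of 20593 genes, with 764 at unadjusted p below 0.05. DESeq2 was not run for it. The smallest adjusted p was 0.0524, for 4933436E23Rik, a gene with no known product that was named here after its values were seen (log2 difference -5.26, SE 0.57). Also named after their values were seen, Serpinb1b had a log2 difference of -6.20 (SE 0.97, adjusted p = 0.264), Rmst -1.50 (adjusted p = 0.228) and Xist -2.10 (adjusted p = 1.0). The count was 0 without control virus replicate 1 (926 at unadjusted p below 0.05), 18 without control virus replicate 2, 60 without Cre virus replicate 1 and 9 without Cre virus replicate 2.

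Gene lists fixed in advance asked whether known neuronal, glial or stress programmes moved together in granule neuron-like nuclei. Lists of long neuronal genes and the short immediate early genes lay lower, and lists of metabolic and immune genes lay higher, in the Cre virus libraries. Of the adhesion and guidance genes, 40 of 41 lay below 0, among them Pcdh15 (ENSMUSG00000052613, log2 fold change -0.69), Cntn4 (-0.56), Epha3 (-0.53) and Dcc (-0.56). All 17 measured ionotropic glutamate receptor genes lay lower, including Grik1 (ENSMUSG00000022935, -0.59), Grik5 (-0.55) and Gria4 (-0.53). limma's camera with a preset correlation of 0.01 called 12 of 29 lists, 7 lower and 5 higher, at a Benjamini-Hochberg adjusted p of 0.05. None of the 12 calls held with an estimated correlation (smallest adjusted p = 0.836 with an estimated correlation), nor with fry (0.914). In each list, 0 genes passed in edgeR, over all genes or adjusted over the list alone, and none of the list genes named here passed with DESeq2. Without control virus replicate 2, 0 of the 12 passed and 6 pointed the other way; 9 stayed past the threshold in their direction without control virus replicate 1, 4 without Cre virus replicate 1 and 3 without Cre virus replicate 2.

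The lower lists were led by axon guidance and adhesion (median log2 fold change -0.31, adjusted p = 3.24e-05) and ionotropic glutamate receptors (-0.23, adjusted p = 0.00267), calls lost with an estimated correlation (adjusted p = 0.836 for both). The others, each at adjusted p = 0.0429, were voltage-gated potassium channels, with 17 of 24 lower (-0.18; Kcnq5 -0.89, Kcnh7 -0.64), epilepsy gene homologues, with 28 of 34 lower (-0.18; Cntnap2 -0.58), neuromodulator receptors, with 12 of 17 lower (-0.25; Drd3 -1.47, Htr2c -0.81, Chrm3 -0.75), immediate early genes, with 16 of 24 lower (-0.17; Fos -0.81, Npas4 -0.74, Nr4a1 -0.61), and the genes often studied with floxed alleles, with 27 of 30 lower (-0.16). Higher were antigen presentation, with 10 of 11 genes higher (0.52, adjusted p = 0.0317; Psmb8 0.87, H2-D1 0.44), and, each at adjusted p = 0.0429, ageing and senescence genes, with 14 of 18 higher (0.23; Cdkn1a 1.08, Serpina3n 0.69), sterol and fatty acid synthesis, with 24 of 32 higher (0.19; Acat2 0.80, Fdps 0.72), glycolysis and hypoxia response, with 19 of 25 higher (0.23; Hk2 1.51, Gapdh 0.68), and interferon response, with 10 of 13 higher (0.20; Sp100 1.39). These calls too were lost (adjusted p = 0.836 with an estimated correlation). The medians of the 12 lists kept their sign under 3 scalings. The log2 fold changes of Cntn4 (0.07), Epha3 (0.20), Cntnap2 (0.11), Chrm3 (0.05) and H2-D1 (-0.05) had the other sign without control virus replicate 2. Hk2 rested on Cre virus replicate 2, at 8.81 and 9.49 CPM in control virus against 10.3 and 43.7 CPM in Cre virus. It passed without Cre virus replicate 1 (2.24, adjusted p = 0.0132) and lay at 0.20 without Cre virus replicate 2 (adjusted p = 1.0).

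The other lists described here did not pass. By camera's direction, lower were voltage-gated sodium and calcium channels (adjusted p = 0.0868, 18 of 22 genes lower), homeostatic microglia genes and GABA-A receptors (0.123 each), vascular and blood cell genes (0.240), neurogenesis and immature granule neuron genes (0.464), Alzheimer disease risk gene homologues (0.60), FoxO targets (0.711), choroid plexus genes and granule neuron identity genes (0.732 each) and oligodendrocyte myelin genes (0.878). Higher were neuropeptides and seizure-related granule neuron genes (0.123 each), the ATF4 and amino acid response (0.272), disease-associated microglia genes (0.442), the p53 and DNA damage response (0.568) and reactive astrocyte genes (0.732). The median and camera's direction differed in sign for FoxO targets (median 0.01), reactive astrocyte genes (-0.06) and oligodendrocyte myelin genes (0.03). Granule neuron identity genes passed downward without control virus replicate 1 (adjusted p = 0.0159) and upward without control virus replicate 2 (0.0209). Vascular and blood cell genes passed upward without control virus replicate 1 (5.67e-04) and downward without control virus replicate 2 (1.50e-09) and Cre virus replicate 1 (0.0136). Oligodendrocyte myelin genes passed upward without Cre virus replicate 1 (0.0415), and neurogenesis genes downward (0.00491). Lists that passed in their direction without control virus replicate 1 were sodium and calcium channels (9.15e-04), GABA-A receptors (0.0159), disease-associated microglia genes (0.00846) and neuropeptides (8.19e-04), the last also without Cre virus replicate 2 (7.00e-05).

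Fold changes in granule neuron-like nuclei followed gene length. Across 15403 tested genes, which are not independent replicates, the Spearman correlation of log2 fold change with gene length was -0.375. In 4 equal bins by length, the median log2 fold change went from 0.21 in the shortest (median length 4319 bases) to -0.15 in the longest (median length 133580 bases). The correlation was 0.108 without control virus replicate 2 and -0.0841 without Cre virus replicate 1, against -0.444 without control virus replicate 1 and -0.397 without Cre virus replicate 2. With the length trend taken out of the gene statistics, 1 of the 12 called lists stayed past the threshold in its direction, the immediate early genes (adjusted p = 0.0083). Like the other called lists, it did not pass in camera with an estimated correlation and the trend kept (adjusted p = 0.836).

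**Figure D2:**
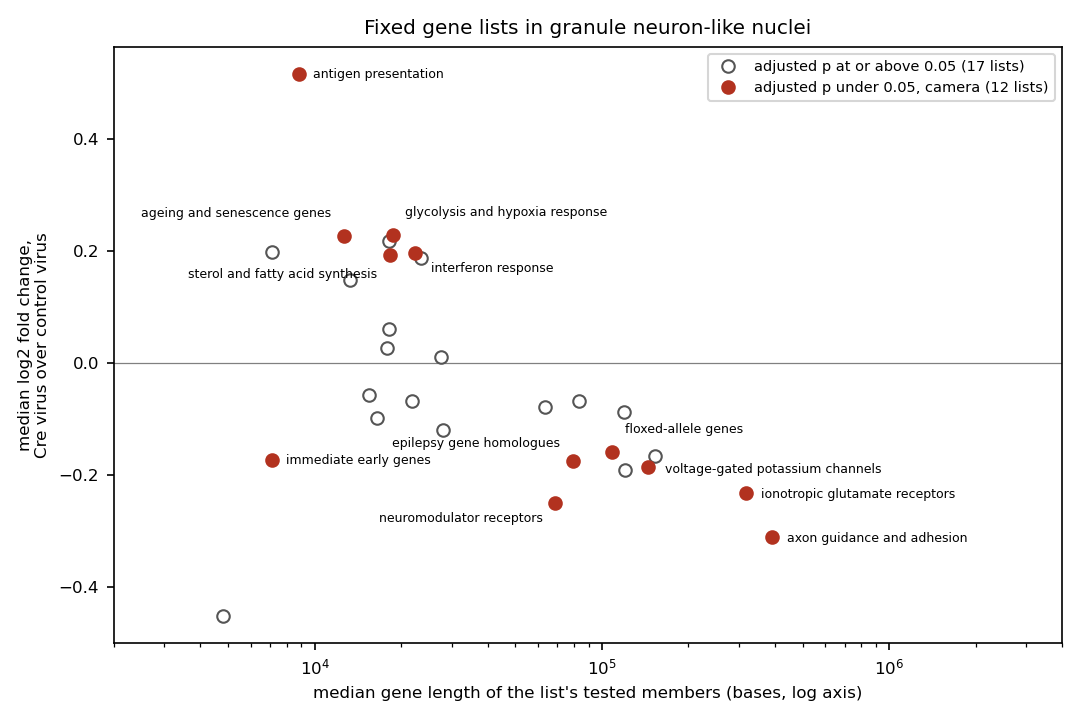
Median log2 fold change of each fixed gene list in granule neuron-like nuclei (Cre virus over control virus) against the median length of its genes in bases (log axis), with called lists marked. Axon guidance and adhesion, a list of long genes, lies at -0.31 and antigen presentation, a list of short genes, at 0.52, while the short immediate early genes lie at -0.17.

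Cell class shares asked whether the composition of the dentate libraries differed with Cre. At the minimum of 500 UMIs per nucleus, granule neuron-like nuclei made up a larger share of both Cre virus libraries, and hippocampal pyramidal neuron-like nuclei a smaller one. Astrocyte-like nuclei were also more frequent in Cre virus, by less at a higher minimum. The granule neuron-like share was 13.7% (Wilson 95% interval 13.2 to 14.3) and 12.3% (11.8 to 12.9) in control virus and 26.3% (25.8 to 26.8) and 32.9% (31.9 to 33.8) in Cre virus, or 13% ± 0.995 (SD, n = 2) against 29.6% ± 4.66 (SD, n = 2). An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow, so no share difference here can reach 0.05. CA1 pyramidal neuron-like nuclei made up 26.5% and 36.0% in control virus against 19.0% and 22.5% in Cre virus, CA2 and CA3 19.7% and 18.4% against 11.4% and 9.32%, and GABAergic interneuron-like 11.8% and 9.46% against 6.97% and 7.28%. Astrocyte-like nuclei made up 3.30% and 2.11% against 9.24% and 5.44%. With all 4 libraries held to a minimum of 1115 UMIs per nucleus, the granule neuron-like shares were 4.77% and 12.3% in control virus and 8.87% and 13.1% in Cre virus, a difference of 2.41 points that lay within the larger SD of 5.35. The pyramidal neuron-like shares overlapped between groups at that minimum, with CA1 at 26.0% and 36.0% against 26.9% and 17.2% and CA2 and CA3 at 30.2% and 18.4% against 27.0% and 16.0%. The astrocyte-like shares were 1.98% and 2.11% against 3.03% and 4.79% there, and their difference went from 4.64 to 1.87 points.

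Mossy cell-like nuclei made up 2.67% and 1.34% of control virus and 1.70% and 1.98% of Cre virus libraries, a difference of -0.171 points that became 2.37 at 1115 UMIs. The difference for GABAergic interneuron-like nuclei went from -3.52 points to 0.894 at that minimum. Oligodendrocyte-like nuclei made up 0.693% and 0.735% against 0.884% and 1.06%, endothelial cell-like 1.67% and 1.27% against 1.63% and 1.13%, and cortical excitatory neuron-like 0.731% and 3.61% against 0.50% and 1.40%. Ependymal cell-like nuclei made up 0.0577% and 0.140% of control virus and 0.170% of Cre virus replicate 1, with 0 of 9519 nuclei in Cre virus replicate 2, which allows a share of up to 0.0315% (3 nuclei of the total). Unnamed clusters held 19.2% and 14.6% in control virus and 22.2% and 17.0% in Cre virus.

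**Figure D3:**
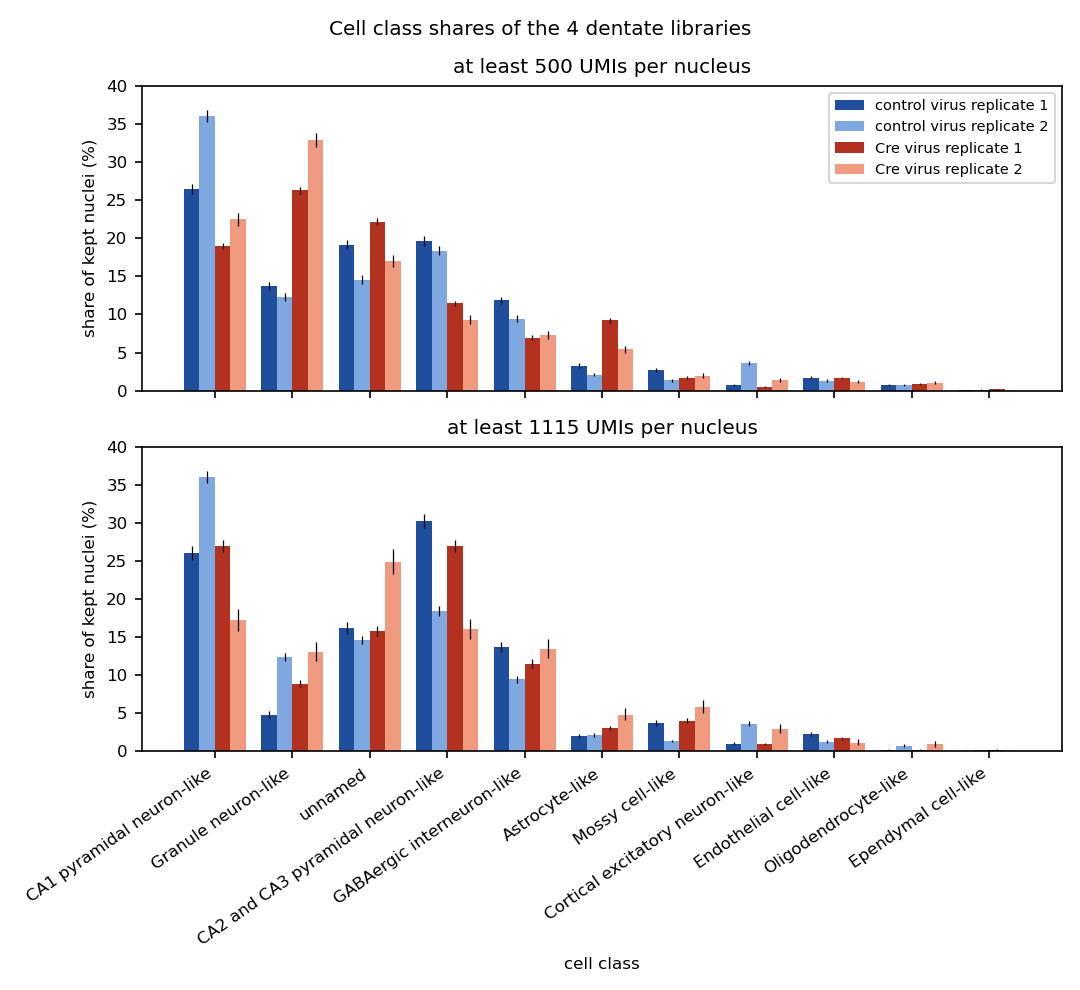
Share of kept nuclei in percent, by cell class, for each of the 4 dentate libraries (bars, with Wilson 95% intervals) at minimums of 500 and 1115 UMIs per nucleus. Granule neuron-like shares of 13.7% and 12.3% in control virus lie below 26.3% and 32.9% in Cre virus at 500 UMIs, and overlap at 1115 UMIs.

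The aged forebrain libraries have no younger group beside them, so their composition is described rather than tested. Cortical excitatory neurons and oligodendrocytes were the most frequent named classes, and astrocyte-like, microglia-like, fibroblast-like, choroid plexus and vascular nuclei differed most as a ratio between the replicates. Cortical excitatory neuron-like nuclei made up 13.4% and 20.4%, or 16.9% ± 4.89 (SD, n = 2), and oligodendrocyte-like nuclei 14.1% and 11.2%, or 12.7% ± 2.03. Astrocyte-like nuclei made up 10.7% of replicate 1 and 1.74% of replicate 2. Striatal medium spiny neuron-like nuclei made up 9.07% and 6.42%, subcortical glutamatergic neuron-like 6.71% and 10.4% (2.31% and 3.48% at clustering resolution 2), and GABAergic interneuron-like 6.80% and 9.91%. Granule neuron-like nuclei made up 2.91% and 3.10%, oligodendrocyte precursor-like 2.21% and 3.34%, CA1 pyramidal neuron-like 1.31% and 2.23%, and CA2 and CA3 0.388% and 0.642%. Microglia-like nuclei made up 1.27% and 0.488%, fibroblast-like 1.41% and 0.256%, endothelial cell-like 0.263% and 0.0744%, pericyte or smooth muscle cell-like 0.256% and 0.00930%, and choroid plexus cell-like 0.134% and 0.0418%. Unnamed clusters held 28.9% and 29.8%.

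**Figure D4:**
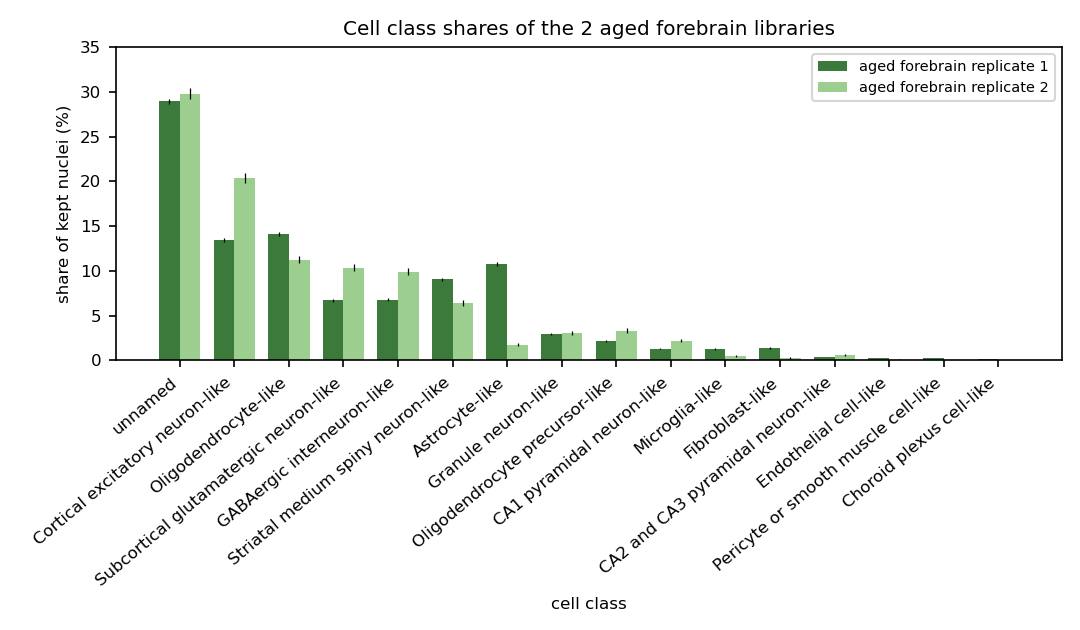
Share of kept nuclei in percent, by cell class, in the 2 aged forebrain libraries, with Wilson 95% intervals for counting error. Astrocyte-like nuclei differ most as a ratio among the larger classes, at 10.7% and 1.74%, while granule neuron-like nuclei lie at 2.91% and 3.10%.

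Within aged forebrain the fixed lists asked which cell types express genes tied to ageing, immunity and excitability. Microglia-like or fibroblast-like nuclei had the most genes higher in the immune lists, astrocyte-like nuclei in the sterol list and cortical excitatory neuron-like nuclei among immediate early genes. Each class was tested against the mean of the other classes with edgeR, with the library as a block. The SE values come from a spread pooled over classes, so they do not measure the spread of a single class between the 2 libraries. Counts per list were not tested between classes, and over all lists 109 to 171 genes were higher, depending on the class. In microglia-like nuclei, 19 of 20 antigen presentation genes were higher (20 adjusted over the list alone), as were 20 of 28 disease-associated microglia genes (22 adjusted over the list alone) and 17 of 32 Alzheimer disease risk gene homologues. All 18 homeostatic microglia genes were higher there too, 12 of them not used as class markers. The protease gene Ctss (ENSMUSG00000038642, chromosome 3, 95526786 to 95556403) measured 7182 and 1108 CPM in microglia-like nuclei, higher by 6.81 on the log2 scale (SE 0.28), and the receptor gene Trem2 (ENSMUSG00000023992) 1713 and 225 CPM (6.6, SE 0.32). The class II chain gene Cd74 (ENSMUSG00000024610) measured 1245 and 78.2 CPM (6.48, SE 0.36). All 3 were lower in replicate 2 in that class. So were the homeostatic microglia genes Selplg (2482 and 326 CPM) and Fcrls (1420 and 167 CPM) and the class II gene H2-Aa (383 and 12.6 CPM). The levels in microglia-like nuclei thus rested mostly on replicate 1, and the gene counts above come from a fit over both libraries together. Why replicate 2 lay lower was not tested.

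Fibroblast-like nuclei, a class of the meninges and vessels, had the most interferon response genes higher. The naming rule did not reject clusters that shared markers of fibroblasts, endothelial cells and pericytes or smooth muscle cells. The pericyte or smooth muscle markers Vtn (3715 and 912 CPM), Acta2 (338 and 18.4 CPM) and Pdgfrb (145 and 67.3 CPM) were also high in this class. Fibroblast-like nuclei may thus include nuclei of those types. Of 30 interferon response genes, 27 were higher there (27 adjusted over the list alone), against 16 in microglia-like and 15 in astrocyte-like nuclei. Isg15 (ENSMUSG00000035692, chromosome 4) measured 73.5 and 98.0 CPM (log2 6.43, SE 0.38) and Ifit1 103 and 196 CPM (6.13, SE 0.29). Fibroblast-like nuclei were few in replicate 2, and the part of UMIs held by single nuclei was not checked in aged forebrain. Also higher in fibroblast-like nuclei were 21 of 26 reactive astrocyte genes, against 19 in astrocyte-like nuclei, and 17 of 20 antigen presentation genes. So were 15 of 28 ageing and senescence genes, 9 of 24 p53 and DNA damage response genes and 6 of 9 choroid plexus genes. All 15 vascular and blood cell genes were higher too, 13 of them not fibroblast markers. Several of those 13, such as Vtn and Acta2, were markers of endothelial cells or of pericytes or smooth muscle cells. Endothelial, pericyte or smooth muscle and choroid plexus cell-like nuclei were too few to be tested in aged forebrain, so vascular and choroid plexus genes are compared among the other classes alone. The complement inhibitor gene Serping1 (ENSMUSG00000023224) measured 742 and 276 CPM there (7.09, SE 0.14).

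Astrocyte-like nuclei had the most genes higher in the lipid and metabolic lists. Of 32 sterol and fatty acid synthesis genes, 28 were higher in them (28 adjusted over the list alone) and 20 in oligodendrocyte-like nuclei. They also led for glycolysis and hypoxia response (14 of 27), FoxO targets (11 of 22) and, level with GABAergic interneuron-like nuclei, the ATF4 and amino acid response (10 of 25). The regulator Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581) measured 470 and 331 CPM in astrocyte-like nuclei (3.29, SE 0.15), the glycolytic gene Aldoc 4014 and 2032 CPM (3.58, SE 0.13) and the glutamate receptor gene Grin2c 286 and 265 CPM (4.64, SE 0.14). All 19 oligodendrocyte myelin genes were higher in oligodendrocyte-like nuclei, 11 of them not class markers. Opalin (ENSMUSG00000050121) measured 1860 and 1022 CPM there (4.78, SE 0.23).

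The class with the most genes higher differed between neuronal lists in aged forebrain. Cortical excitatory neuron-like nuclei led for immediate early genes (20 of 28 higher), epilepsy gene homologues (22 of 34), voltage-gated potassium channels (16 of 24), voltage-gated sodium and calcium channels (17 of 23) and the genes often studied with floxed alleles (15 of 30). CA2 and CA3 pyramidal neuron-like nuclei led for axon guidance and adhesion (22 of 41) and expressed the immediate early gene Ptgs2 (ENSMUSG00000032487) at 176 and 54.0 CPM (4.07, SE 0.29). Subcortical glutamatergic neuron-like nuclei led for GABA-A receptors (10 of 14), seizure-related granule neuron genes (12 of 21) and neurogenesis and immature granule neuron genes (12 of 25), counted at clustering resolution 1 alone, although the extent of this class depended on the resolution. Striatal medium spiny neuron-like nuclei led for neuromodulator receptors (14 of 25), with the dopamine receptor gene Drd2 (ENSMUSG00000032259) at 131 and 68.7 CPM (4.06, SE 0.21). GABAergic interneuron-like nuclei led for neuropeptides (17 of 24, of which 13 were not class markers), with Crh (ENSMUSG00000049796) at 53.2 and 35.3 CPM (4.47, SE 0.21). Granule neuron-like nuclei led for granule neuron identity genes (20 of 22, of which 10 were not class markers) and ionotropic glutamate receptors (9 of 18), and expressed the growth factor gene Bdnf (ENSMUSG00000048482) at 158 and 90.7 CPM (2.38, SE 0.17). Every gene named here for aged forebrain passed a Benjamini-Hochberg adjusted p of 0.05 and was higher in its class than in the mean of the others in the fit over 2 libraries.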

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

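The count of classes for Xist and Eif2s3y and both tests of the granule neuron-like share were chosen after the results were seen. For the other explanations, rules were fixed before their tests, but after the patterns they concern had been seen. The patterns, and control virus replicate 2 as the library to test, were taken from these same data.

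Cre virus effects on 8 of 29 gene lists differed between granule neuron-like nuclei and the other named classes together, by camera with a preset correlation of 0.01. The make-up of that pool also differed between the groups (mean astrocyte-like share of all nuclei 2.70% against 7.34%, CA1 31.2% against 20.7%), so composition and expression are not separated in it. Relative to the other classes, granule neuron identity genes (adjusted p = 3.56e-05), oligodendrocyte myelin genes (3.56e-05), disease-associated microglia genes (5.33e-05), ageing and senescence genes (2.76e-04), reactive astrocyte genes (0.00455), homeostatic microglia genes (0.0181) and antigen presentation (0.0377) were lower in granule neuron-like nuclei, and axon guidance and adhesion (0.0167) was higher. None held with an estimated correlation (smallest adjusted p = 0.535). Without control virus replicate 2, axon guidance (0.804), homeostatic microglia genes (0.804) and antigen presentation (0.190) did not pass, without Cre virus replicate 2 homeostatic microglia genes (0.161), antigen presentation (0.265) and reactive astrocyte genes (0.0983) did not, without control virus replicate 1 antigen presentation (0.0844) and reactive astrocyte genes (0.197) did not, and without Cre virus replicate 1 axon guidance (0.0663) did not.

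RNA of the tomato feature was counted in Cre virus replicate 2 at 7.80 CPM, and no other library lists the feature, so it cannot be compared between groups.

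The loss of Xist and gain of Eif2s3y in the Cre virus libraries may reflect animals of different sex behind the groups, which the labels do not give. Xist was lower and Eif2s3y higher in both Cre virus libraries in 9 of 9 tested classes, which restates the pattern over classes of the same 4 libraries, so a difference in sex was not tested and stays open. The Y-linked Ddx3y and Uty were not absent from control virus, at 68.7 and 27.9 CPM and 13.5 and 17.7 CPM over all nuclei against 155 and 173 CPM and 63.5 and 93.9 CPM in Cre virus, and Ddx3y reached 289 CPM in granule neuron-like nuclei of control virus replicate 1 (133 of 613 UMIs in 1 nucleus), so these 2 genes stay unexplained. Cre acting in granule neurons alone, with their RNA spread to other nuclei as free RNA, was not decided by the rule fixed before. To set it aside, that rule asked for at least 0.5 times the granule neuron-like Xist level in every other class. In control virus 7 of 8 classes reached it, but endothelial cell-like nuclei lay at a mean of 0.234 times. Oligodendrocyte-like nuclei, the highest class, lay at 1.21 and 1.43 times (mean 1.32). Free RNA taken from granule neurons would lie below 1, which argues against the explanation for that class alone. If the groups do differ in sex, an effect of Cre on a gene could not be told from an effect of sex.

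The lower lists of neuronal genes and higher lists of metabolic and immune genes in granule neuron-like nuclei could stem from a gene length bias between libraries. With the length trend taken out, 1 of 12 called lists stayed past the threshold, the immediate early genes, which fits a length bias for the other lists. No list, the immediate early genes included, passed in camera with an estimated correlation (smallest adjusted p = 0.836). Control virus replicate 2 standing apart met its rule as well, as 0 of 12 lists stayed past the threshold without it. That fit left 1 control virus library, and most calls were also lost without either Cre virus library, so lost calls cannot single it out. Without control virus replicate 2, 6 of the 12 lists pointed the other way. That number was 0 without control virus replicate 1, 1 without Cre virus replicate 1 and 0 without Cre virus replicate 2. An effect of Cre on granule neurons beyond that on other classes cannot be told, as 0 of 12 lists passed in the same direction in the test of the difference and 3 passed in the opposite direction. The pattern is not called biological.

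The larger granule neuron-like share in the Cre virus libraries could come from the smallest UMI count per deposited barcode, which was lower there. At a common minimum of 1115 UMIs the difference between groups was 2.41 points, against 16.5 points before. With 14.6% of it kept and a larger SD of 5.35 points, the rule for that explanation was met. Granule neuron-like nuclei had medians of 887 and 1338 UMIs in control virus and 766 and 665 UMIs in Cre virus. The cut therefore removed many of them from the shallower libraries, so it cannot tell the deposited minimum from depth. More dentate gyrus in the Cre virus tissue might also play a part, and mossy cell-like shares, in a ratio of 1.93 at that minimum and 0.915 at 500 UMIs, cannot tell. The pattern is not called biological.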

How the results depend on the processing

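Leaving out X- and Y-linked genes, leaving out the top nucleus of each gene, and the common minimum of 1115 UMIs were chosen after the results were seen, and all other alternatives were fixed before.

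In granule neuron-like nuclei, 2 calls became 1 with library totals alone, 75 with no filter on low counts, 39 with a replicate block, 7 with DESeq2 (164 genes at unadjusted p below 0.05) and 0 by edgeR without X- and Y-linked genes (172 at unadjusted p below 0.05; DESeq2 was not run so). Other settings gave 2 or 3. Leaving out 1 library gave 0 to 49. Over all nuclei, 4 calls became 1 with library totals alone, 65 with no filter, 1 with at least 10 CPM in at least 2 libraries, 71 with a replicate block, 9 with DESeq2, 2 with at least 1000 UMIs per nucleus, 2 with doublets kept, 2 with libraries thinned to the same total and 0 by edgeR without X- and Y-linked genes (364 at unadjusted p below 0.05). Leaving out 1 library gave 2 to 105. The labels do not say whether replicates were paired, and deviations from group means correlated at 0.318 in granule neuron-like and 0.222 over all nuclei, across genes; genes are not independent replicates.

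With no filter and with a replicate block, calls were 61 and 57 in astrocyte-like, 88 and 27 in CA1, 77 and 39 in CA2 and CA3, 59 and 11 in cortical, 39 and 4 in endothelial, 67 and 23 in GABAergic, 76 and 12 in mossy cell-like and 27 and 5 in oligodendrocyte-like nuclei. With the top nucleus of each gene left out, CA2 and CA3, endothelial and mossy cell-like nuclei had 4 each. Leaving out 1 library gave 4 to 261 in astrocyte-like, 3 to 87 in CA1, 7 to 1095 in CA2 and CA3, 15 to 77 in cortical, 18 to 119 in endothelial, 5 to 870 in GABAergic, 11 to 171 in mossy cell-like and 0 to 22 in oligodendrocyte-like nuclei. The difference between granule neuron-like and other classes gave 1 call with RLE scaling, 95 with no filter and 0 to 60 with 1 library left out.

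Of 547 values for 60 named dentate genes outside leaving out a library, 502 stayed on the same side of the threshold. A call was lost in 15 and gained in 30. The 502 include genes named as not passing that still did not pass. All 327 values for 109 named genes in aged forebrain kept their call. For lists, calls went from 12 to 0 with an estimated correlation, to 0 with fry, and to 2 to 16 with 1 library left out. Oligodendrocyte myelin genes pointed up with fry (adjusted p = 0.991). Of 112 list values with 1 library left out, 28 had the other direction.

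Log2 fold changes went, with control virus replicate 1 and then replicate 2 left out, from 1.08 to -0.0470 for H2-D1, -1.004 to 0.0705 for Cntn4, -1.02 to 0.20 for Epha3, -1.26 to 0.0458 for Chrm3 and -1.05 to 0.11 for Cntnap2. Adjusted p-values of lists that changed direction with a library left out ranged over these values: genes often studied with floxed alleles 4.67e-05 to 0.336, FoxO targets 0.318 to 0.810, sterol and fatty acid synthesis 0.00280 to 0.864, p53 and DNA damage response 0.459 to 0.961, antigen presentation 0.00560 to 0.961, reactive astrocyte genes 0.189 to 0.804, disease-associated microglia genes 0.00846 to 0.864, and neurogenesis genes 0.00491 to 0.778. They ranged from 0.0159 to 0.244 for granule neuron identity genes, 0.0159 to 0.699 for GABA-A receptors, 4.24e-05 to 0.405 for potassium channels, 9.15e-04 to 0.459 for sodium and calcium channels, 3.04e-12 to 0.338 for axon guidance and adhesion, 7.00e-05 to 0.336 for neuropeptides, 0.406 to 0.874 for Alzheimer disease risk gene homologues, 0.00770 to 0.554 for ageing and senescence genes, 5.67e-04 to 0.537 for epilepsy gene homologues, 0.0415 to 0.540 for oligodendrocyte myelin genes, 1.50e-09 to 0.789 for vascular and blood cell genes and 0.424 to 0.804 for choroid plexus genes.

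Share differences in points, Cre virus minus control virus, at 1000 and at 1115 UMIs were 1.95 and 1.87 for astrocyte-like, -3.17 and -2.82 for CA2 and CA3, 0.597 and 0.894 for GABAergic, 3.85 and 2.41 for granule neuron-like, 1.88 and 2.37 for mossy cell-like and 0.0490 and 0.0974 for oligodendrocyte-like nuclei. In aged forebrain the mean share went from 0.515% to 0.767% for CA2 and CA3 at resolution 0.5, from 8.36% to 11.1% for GABAergic and from 8.54% to 2.90% for subcortical glutamatergic at resolution 2, and from 3.01% to 3.17% for granule neuron-like at 1000 UMIs. For unnamed it went from 29.4% to 28.4%, 31.0% and 36.4% at 1000 UMIs and resolutions 0.5 and 2. At 1000 UMIs, 10854 nuclei were kept in control virus replicate 1, 14273 and 3330 in Cre virus replicates 1 and 2 and 71699 in aged forebrain replicate 1.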

Other observations

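The values in this part were chosen after the data were seen, and none was tested.

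Several groups of aged forebrain nuclei that were left without a class name had genes of known neuromodulatory and hypothalamic cells at their top. A group of 97 nuclei (65 and 32 per library) led with the dopamine and serotonin genes Slc6a3, Th, Ddc, Tph2 and Slc6a4, and a group of 87 (71 and 16) with the acetylcholine genes Slc5a7 and Chat. Oxt, Avp and Pmch led a group of 50 (30 and 20), and Gal, Hcrt, Trh and Gnrh1 a group of 1941 (1412 and 529). A group of 29 nuclei, all from replicate 1, had the T cell genes Cd3g, Nkg7 and Ccl5 among its top genes and was left unnamed because it held fewer than 30 nuclei, and the cell division genes Top2a and Hmgb2 led a group of 16 (15 and 1).

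In both aged forebrain libraries Xist was low, at 0.414 and 1.66 CPM, and Eif2s3y was present, at 137 and 132 CPM. Kdm5d lay at 41.9 and 53.2 CPM there.

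Among dentate nuclei without a class name, a cluster of 4226 nuclei held microglial genes such as P2ry12 and Csf1r beside the neuronal genes Neurod1, Prox1 and Sox11 among its top genes. A cluster of 4643 nuclei led with Cox6c, Cox6a1 and Ndufa4 and had a median of 3.58% mitochondrial UMIs. A cluster of 543, with 176 and 256 nuclei in control virus and 74 and 37 in Cre virus, had Ano1, Meis2, Zic4 and Zic1 among its top genes. A cluster of 32 came from control virus replicate 2 alone.

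Single nuclei sometimes held a large part of the UMIs of a gene in a library. In endothelial cell-like nuclei of Cre virus replicate 2, 1 nucleus held 53 of 60 S100a10 UMIs. In granule neuron-like nuclei of control virus replicate 1, 1 nucleus held 133 of 613 Ddx3y UMIs and 113 of 511 Sim1 UMIs.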
